A study of Homo sapiens with 12 samples.

How the data were processed

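Human foreskin fibroblasts infected with human cytomegalovirus were profiled on 12 arrays of total RNA, 1 for each of 0.5, 1, 4, 6, 10, 12, 14, 16, 18, 20, 24 and 48 h after infection, per the labels. The groups were the times in the titles. Only the 24 h label names a viral strain and calls the cells primary, and the labels do not say whether the arrays came from 1 infection or from several. The probe set names are those of an Affymetrix array with 12626 probe sets.

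For 11 arrays the deposited values are linear intensity values, 1 per probe set. How the authors summarised probes, subtracted background and scaled these intensity values is not given in the sources used here. Their medians differed between arrays, from 1364 to 1779, so they had not been made equal in distribution. The highest values on each array lay between 30032 and 33203, where brightness may be compressed, so large differences between bright probe sets can be understated. In all 11 arrays 417 probe sets were blank. The 48 h values are another unit: the deposited table gives signed fold changes with 1 decimal, at or above 1 or at or below -1, with none between. Their comparator, direction and computation are not given in the sources used here. The planned contrast of 48 h with 10 to 24 h needed an intensity at 48 h and was not run, and the other models used 11 arrays instead of 12. The 48 h folds were only described.

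Intensities of non-control probe sets were quantile normalized between arrays with limma 3.58.1 in R 4.3.3. Values were then raised to a floor at the 10th percentile of all values, 315 intensity units, and put on the log2 scale, so a difference that involves values at the floor is understated. Probe sets above the floor on at least 3 arrays were tested, 11353 of the 12143 non-control probe sets with intensities. The 67 array control probe sets were left out of the tests, as were 15 probe sets of sex chromosome genes. Gene symbols came from the platform annotation: 10961 probe sets had 1 gene symbol, 546 had several and 1119 had no annotation, and none was named from a probe set with several. No symbol changed when matched by gene identifier to the RefSeq gene table of GRCh38.p14, which was used only for names. The tested probe sets covered 7617 genes, and where a gene had several probe sets the brightest on average stood for it. Probe sets whose name ends in _s_at or _f_at can detect related transcripts.

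Linear models were fitted with lmFit and eBayes of limma and adjusted by the Benjamini-Hochberg method at 0.05. The trend was a slope on log2 hours with 9 residual degrees of freedom. The smooth change was an F test on a natural spline with 3 degrees of freedom, leaving 7. Windows of 0.5 to 1, 4 to 6 and 10 to 24 h each had a mean, leaving 8 residual degrees of freedom. Because no time had a replicate, neighbouring times stood in for replicates, and the error holds both array noise and true change within a window. The p-values measure only this spread, which may be technical, and do not cover differences between independent infections. The 2 comparisons against 0.5 to 1 h share those 2 arrays. With no uninfected arrays, changes with time in culture or after handling cannot be separated from changes with infection.

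A set of 23 gene lists, with 655 genes of which 526 were measured, the tests, the alternatives and the rule for naming genes were fixed before the data were examined. The lists covered interferon-stimulated genes, antigen presentation, cytokines, immediate early response, G1/S and DNA replication, G2 and mitosis, p53 targets, extracellular matrix, matrix proteases, actin cytoskeleton, unfolded protein response, heat shock, sterol and fatty acid synthesis, glycolysis, oxidative phosphorylation, ribosomal proteins, proteasome, prostaglandin synthesis, and markers of keratinocytes, endothelial cells, leukocytes, melanocytes and fibroblasts. Lists with at least 5 measured genes were tested with camera, which compares a list with all other genes, at a preset correlation between genes of 0.01, over 66 tests. Of these, 17 passed with the preset correlation and 0 with an estimated correlation, so each set call rests on the preset value. fry, which asks whether the genes of a list move on balance in 1 direction and does not compare lists with other genes, called 27, and its test for change in either direction called 55. Where a list's median and mean differed in sign, as for antigen presentation and prostaglandin synthesis genes at 10 to 24 h, the set did not pass. The genes named are, per comparison, the 8 largest rises and 8 largest falls past the threshold with 1 gene symbol, up to 4 members of each list with the smallest p, the 8 smallest p for the spline, and a panel of 15 genes given whatever their values. Fewer are printed for length, and a few 48 h folds were chosen after their values were seen.

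For 48 h, the median signed log2 fold of each list was set against 10000 random lists of the same size matched on mean intensity, with NumPy 2.4.6 and pandas 2.3.3 in Python 3.11.15. Figures were drawn with matplotlib 3.10.9.

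The models were tested on simulated data of 11353 probe sets with 200 changed. The simulated noise was normal and independent between probe sets and between arrays, and far fewer probe sets were changed than were called in the data. Recovery and false calls in the real data may therefore differ. Of probe sets changed 2-fold and 4-fold, the trend recovered 51% and 97%, the spline 32% and 85%, the 4 to 6 h comparison 59% and 97%, and the 10 to 24 h comparison 76% and 100%. A narrow peak at 6 h was recovered by the spline in 1% and 27%. Alternatives were scaling to the 75th percentile, no normalization, other floors and filters, a variance trend with robust estimation, array weights (whose estimation stopped before full convergence in some fits), the GAPDH 3′ over 5′ control ratio as covariate, other time scales and spline degrees of freedom, a wider early window, other list settings, and leaving out each array in turn. A contrast of 10 to 24 h with 4 to 6 h, the actin 3′ over 5′ ratio as covariate and fits without the 6 h and 18 h arrays were added after the data were seen.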

Results

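Transcript levels were measured on 12 arrays of human foreskin fibroblasts, connective tissue cells grown in culture, after infection with human cytomegalovirus (HCMV), a herpesvirus. Each array represented a different time after infection, from 0.5 h to 48 h, and no uninfected culture was among the samples. The label of the 24 h array names the AD169 laboratory strain. For 11 arrays, 0.5, 1, 4, 6, 10, 12, 14, 16, 18, 20 and 24 h, the deposited values were linear intensities, with medians over probe sets of 1364 to 1779. The 48 h values were signed fold changes against a comparator that is not stated, so they are described separately. No time had a replicate. Neighbouring times were combined into windows of 0.5 to 1 h (2 arrays), 4 to 6 h (2 arrays) and 10 to 24 h (7 arrays), and the scatter within windows served as error. With 11 arrays, their number limits the precision. Normalized log2 intensities correlated at Pearson r of 0.942 to 0.986 across probe sets between neighbouring times, and at 0.884 between 0.5 h and 24 h (probe sets are not independent replicates). The first principal component held 60.8% of the variance and ran from -55.3 at 1 h to 41.6 at 18 h. Gene lists were tested with camera, and no list passed with an estimated correlation between genes, so each set that passed is given with that p-value too. Differences below are log2 differences of normalized intensity ± standard error from limma, with Benjamini-Hochberg adjusted p.

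**Figure D1:**
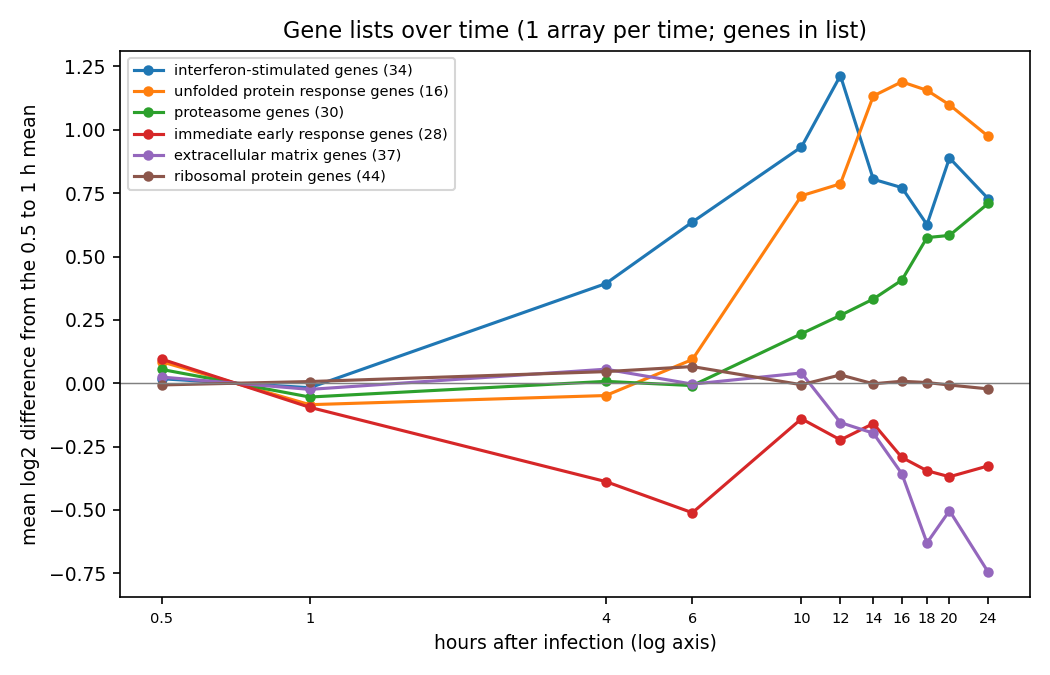
Mean log2 difference from the 0.5 to 1 h mean (vertical axis) against hours after infection on a log axis, with 1 array per point and the number of measured genes of each list in the legend. The interferon-stimulated list of 34 genes lay above 0 on every array from 4 h on and the extracellular matrix list of 37 genes lay below 0 on every array from 12 h on.

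The comparison of 4 to 6 h with 0.5 to 1 h asked which transcripts moved in the early hours. ISG15, an interferon-induced ubiquitin-like protein, rose by 2.82 ± 0.21 (adjusted p = 0.000102), a 7.05-fold difference between 2 arrays and 2 arrays. IFIT1, an interferon-induced RNA-binding protein, rose by 2.06 ± 0.18 (adjusted p = 0.000336), and MX1, an antiviral GTPase, by 1.37 ± 0.26 (adjusted p = 0.0184). ZC3HAV1, the zinc finger antiviral protein, rose by 2.53 ± 0.54 and IFIT3 by 2.90 ± 0.66. The zinc finger gene ZNF473 had the highest rise of the named genes, 4.31 ± 0.24, with 1 of the 2 early arrays at the intensity floor, and the apoptosis regulator PMAIP1 rose by 2.93 ± 0.40. HEXIM1, an inhibitor of the elongation factor P-TEFb, was at the floor on both early arrays and was at least 3.9-fold higher at 4 to 6 h (adjusted p = 0.0306).

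Among the falls, ZFP36, which promotes decay of AU-rich mRNAs, changed by -4.20 ± 0.51 (adjusted p = 0.00222), and the matricellular gene CCN1 by -3.60 ± 0.42 (adjusted p = 0.00208). The peptide hormone gene ADM changed by -3.06 ± 0.21 (adjusted p = 6.74e-05), and the transcription regulator genes CITED2 and JUN by -2.57 ± 0.31 and -2.13 ± 0.29. SNAI2, a transcription factor of mesenchymal cells, was at the floor on both later arrays and was at least 5.3-fold lower (adjusted p = 0.00449).

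By list, 5 of 34 measured genes rose and 1 fell among interferon-stimulated genes (9 higher and 1 lower adjusted over the list alone). The median of this list was 0.17 (adjusted p = 0.00883, and adjusted p = 0.801 with an estimated correlation), and -0.02 without normalization. The gene that fell, IRF1, an interferon-regulated transcription factor, changed by -0.84 ± 0.18. Among immediate early response genes, 4 of 28 measured genes rose and 7 fell (4 higher and 9 lower adjusted over the list alone). Their median was -0.23 (adjusted p = 0.0161, and adjusted p = 0.772 with an estimated correlation), and without the 0.5 h array the set did not pass (adjusted p = 0.0685). SGK1, a serum-induced kinase, changed by -1.16 ± 0.15, whereas FOS measured -0.96 ± 0.41 (adjusted p = 0.188) and EGR1 0.11 ± 0.23 (adjusted p = 0.836). Of cytokine, chemokine and NF-kB target genes, 4 of 26 measured genes rose and 0 fell (6 higher and 1 lower adjusted over the list alone). The prostaglandin synthase PTGS2 rose by 1.81 ± 0.42, TNFAIP6 2.83-fold, NFKB1 by 0.80 ± 0.14 and TNFAIP2 by 0.54 ± 0.12. This list did not pass as a set (adjusted p = 0.126, and adjusted p = 0.772 with an estimated correlation). CXCL8 measured 0.93 ± 0.46 (adjusted p = 0.25) and IL6 -0.93 ± 0.83 (adjusted p = 0.554). Oxidative phosphorylation genes had a median of -0.13 (adjusted p = 0.0256, and adjusted p = 0.772 with an estimated correlation). The only member past the threshold, CYCS, which encodes cytochrome c, rose by 0.58 ± 0.14 (0 higher and 0 lower adjusted over the list alone). This set did not pass with scaling to the 75th percentile (adjusted p = 0.198), without the 0.5 h array (adjusted p = 0.420) or without the 4 h array (adjusted p = 0.0732). Among G1/S and DNA replication genes, 0 of 42 measured genes rose and 1 fell (0 higher and 0 lower adjusted over the list alone), RFC4 being that gene, and among unfolded protein response genes 1 of 16 measured genes rose and 0 fell (2 higher and 1 lower adjusted over the list alone), XBP1 being that gene. Neither of these lists passed as a set (adjusted p = 0.932 and 0.932).

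In this comparison 668 of 11353 probe sets passed the threshold, 366 higher and 302 lower, and 109 of the higher and 177 of the lower differed by at least 2-fold. The GAPDH 3′ over 5′ control ratio was 0.937 and 0.960 at 0.5 h and 1 h and 0.862 and 0.867 at 4 h and 6 h. On the 6 h array the 18S ribosomal RNA 5′ control read 9039 and the antisense actin control 10690. The share of calls that were higher was 54.8% after quantile normalization, 61.8% with scaling to the 75th percentile and 18.1% without normalization. The median deposited log2 intensity differed from that at 0.5 h by -0.20 at 4 h, -0.22 at 6 h and 0.16 at 24 h. The count was 60 without the 1 h array, 237 without the 4 h array, 51 without the 6 h array, 445 without the 16 h array, 276 with the GAPDH 3′ over 5′ ratio as covariate, 1009 with the actin ratio and 1478 with array weights. Without the 6 h and 18 h arrays 37 probe sets passed. Of the 41 named genes 21 passed with the GAPDH ratio and 10 in every leave-one-out fit, namely ISG15, IFIT1, ZNF473, CSRNP2, ADM, CCN1, CITED2, SGK1, SNAI2 and ZFP36.

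**Figure D2:**
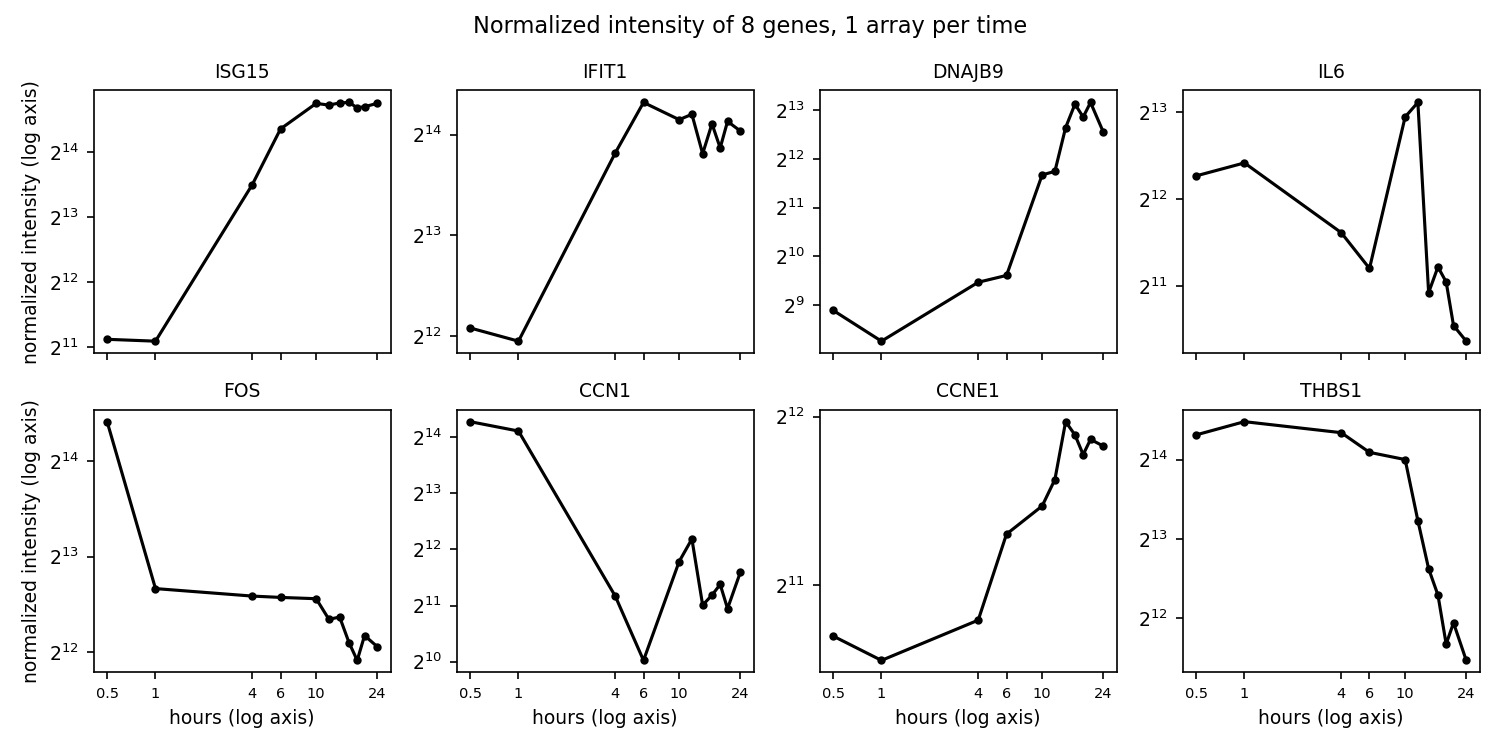
Normalized intensity (log axis, a separate range in each panel) against hours after infection (log axis) for 8 genes, with 1 array per point and no error bars because no time had a replicate. ISG15 and IFIT1 were higher from 4 h on than at 0.5 h and 1 h, DNAJB9 read 706 and 779 at 4 h and 6 h and 3262 at 10 h, and IL6 reached 7905 and 8875 at 10 h and 12 h against 2358 at 6 h.

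The comparison of 10 to 24 h with 0.5 to 1 h asked what differed later in the course of the first day. DNAJB9, a chaperone cofactor of the endoplasmic reticulum, rose by 3.94 ± 0.38 (adjusted p = 4.93e-05), a 15.4-fold difference between 7 arrays and 2 arrays, with 1 early array at the floor. The tumour necrosis factor family ligand TNFSF9 rose by 3.81 ± 0.55 (adjusted p = 0.000413), ISG15 by 3.62 ± 0.17 (adjusted p = 6.19e-07) and MX1 by 2.68 ± 0.21. LIG4, the DNA ligase of non-homologous end joining, rose by 3.03 ± 0.31, the nuclear pore gene NUP58 by 3.09 ± 0.28, PMAIP1 by 3.28 ± 0.32 and the histone chaperone gene ANP32E by 2.90 ± 0.32. For NUP58 1 early array was also at the floor. TCF21, a transcription factor of mesenchymal cells, changed by -3.42 ± 0.39 (adjusted p = 0.000113), with 3 of 7 later arrays at the floor. ADM changed by -3.20 ± 0.17 (adjusted p = 1.90e-06), the transcription factor OSR2 by -3.19 ± 0.28, the secreted Wnt inhibitor DKK1 by -3.02 ± 0.63, and GAP43 by -3.10 ± 0.61.

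Of interferon-stimulated genes, 21 of 34 measured genes rose and 0 fell (21 higher and 0 lower adjusted over the list alone). The median of this list was 0.66 (adjusted p = 0.000829, and adjusted p = 0.772 with an estimated correlation). Examples were IFIT1 at 2.03 ± 0.15 and ISG20 at 1.09 ± 0.18. Antigen presentation genes did not pass as a set (adjusted p = 0.932), with 2 rises and 0 falls of 14, among them the peptide transporter TAP1 at 1.68 ± 0.21. Of unfolded protein response genes, 10 of 16 measured genes rose and 1 fell (12 higher and 1 lower adjusted over the list alone), with a median of 0.74 (adjusted p = 0.00146, and adjusted p = 0.772 with an estimated correlation). DNAJC3, an inhibitor of the kinase PERK, rose by 2.30 ± 0.28, SEL1L, of the degradation machinery of the endoplasmic reticulum, by 1.52 ± 0.15, and the chaperone HSPA5 by 0.44 ± 0.09 (adjusted p = 0.00381). Among proteasome genes 14 of 30 measured genes rose and 1 fell (14 higher and 1 lower adjusted over the list alone), with a median of 0.45 (adjusted p = 0.00674, and adjusted p = 0.801 with an estimated correlation). PSMC4 rose by 1.19 ± 0.23 and PSMD3 by 1.17 ± 0.21, both encoding subunits of the regulatory particle. Heat shock genes had 8 rises and 1 fall among 18 genes (8 higher and 1 lower adjusted over the list alone, adjusted p = 0.026, and adjusted p = 0.772 with an estimated correlation). Without the 0.5 h array this set did not pass (adjusted p = 0.0685). Members included DNAJA1 at 1.74 ± 0.12 and HSPA2 at 1.49 ± 0.16. For HSPA4 another probe set was called in the opposite direction.

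By median, extracellular matrix genes went the other way, at -0.26 (adjusted p = 0.0312, and adjusted p = 0.828 with an estimated correlation). Of 37 measured genes 1 rose and 6 fell (1 higher and 5 lower adjusted over the list alone). Over all 11353 tested probe sets 2183 rose and 2185 fell, so falls were no more frequent in this list, while rises were scarcer. The set did not pass with scaling to the 75th percentile (adjusted p = 0.0671) or without the 0.5 h, 18 h or 24 h array (adjusted p = 0.137, 0.0546 and 0.0603). Collagen genes COL3A1 and COL4A1 changed by -1.37 ± 0.29 and -0.69 ± 0.14, and the collagen chaperone SERPINH1 by -1.26 ± 0.34, while PLOD2, a collagen lysyl hydroxylase, rose by 0.79 ± 0.17. COL1A1 measured -0.64 ± 0.45 (adjusted p = 0.277) and the matricellular gene THBS1 fell, with -1.93 ± 0.54 (adjusted p = 0.0154). Among sterol and fatty acid synthesis genes 1 of 23 measured genes rose and 6 fell (1 higher and 6 lower adjusted over the list alone), with a median of -0.29 (adjusted p = 0.0407, and adjusted p = 0.801 with an estimated correlation). This set did not pass with scaling to the 75th percentile (adjusted p = 0.0832) or without the 0.5 h, 14 h or 18 h array (adjusted p = 0.141, 0.0501 and 0.0546). SREBF1, a transcription factor of lipid synthesis, changed by -0.79 ± 0.15 and SC5D, a cholesterol synthesis enzyme, rose by 1.36 ± 0.14. Actin cytoskeleton and contractile genes had 0 rises and 5 falls among 24 (0 higher and 2 lower adjusted over the list alone), without passing as a set (adjusted p = 0.0624, and adjusted p = 0.801 with an estimated correlation). With scaling to the 75th percentile the list had 0 rises and 3 falls, and without normalization 1 rise and 3 falls. The adhesion protein ZYX changed by -0.88 ± 0.24.

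Growth and stress lists held members in both directions. Among G1/S and DNA replication genes 12 of 42 measured genes rose and 8 fell (12 higher and 8 lower adjusted over the list alone, set adjusted p = 0.606). The flap endonuclease FEN1 rose by 2.66 ± 0.38, CCNE2, an S-phase cyclin, by 1.19 ± 0.23 and CCNE1 by 1.15 ± 0.16, although another CCNE1 probe set was called lower. TYMS, thymidylate synthase, measured -0.31 ± 0.21 (adjusted p = 0.264). Among G2 and mitosis genes 3 of 32 measured genes rose and 5 fell (3 higher and 5 lower adjusted over the list alone, set adjusted p = 0.754), with the phosphatase CDC25B at -1.56 ± 0.22 and PTTG1 at 1.03 ± 0.13. The mitotic cyclin CCNB1 measured 0.49 ± 0.19 (adjusted p = 0.0658). Immediate early response genes had 8 rises and 11 falls among 28 (8 higher and 12 lower adjusted over the list alone, set adjusted p = 0.423), including falls of MYC at -1.52 ± 0.21 and FOS at -1.32 ± 0.33. Of cytokine, chemokine and NF-kB target genes 6 of 26 measured genes rose and 4 fell (6 higher and 5 lower adjusted over the list alone, set adjusted p = 0.754). TNFAIP6 rose by 2.10 ± 0.22 and CXCL8 by 1.10 ± 0.37. The chemokines CCL2 and CCL7 changed by -1.85 ± 0.36 and -1.38 ± 0.23, and IL6 measured -0.89 ± 0.66 (adjusted p = 0.312). Of p53 target genes 2 of 12 measured genes rose and 3 fell (2 higher and 4 lower adjusted over the list alone, set adjusted p = 0.302), with CDKN1A at -0.52 ± 0.14 and the DNA repair gene XPC at -1.76 ± 0.24. Prostaglandin synthesis genes had 2 rises and 2 falls among 11 (3 higher and 2 lower adjusted over the list alone, set adjusted p = 0.899). PTGS2 rose by 1.59 ± 0.34, and the phospholipase PLA2G4A, at the floor on both early arrays, was at least 4.44-fold higher. Glycolysis genes had 3 rises and 2 falls among 18 (2 higher and 1 lower adjusted over the list alone, set adjusted p = 0.926), and oxidative phosphorylation genes 8 and 6 among 53 (7 higher and 6 lower adjusted over the list alone, set adjusted p = 0.847). Matrix proteases and inhibitors had 0 and 2 among 16 (0 higher and 2 lower adjusted over the list alone, set adjusted p = 0.302), including the protease PLAU at -1.34 ± 0.27. Ribosomal protein genes had 0 rises and 0 falls among 44 in limma (0 higher and 0 lower adjusted over the list alone, set adjusted p = 0.934). Their mean log2 level was 14.44 at 0.5 h and 14.43 at 24 h, against a median of 10.78 over all tested probe sets. Compression of bright values may therefore hide change in this list.

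In all, 4368 of 11353 probe sets passed, 2183 higher and 2185 lower, and 809 and 785 of them differed by at least 2-fold. The control GAPDH 3′ over 5′ ratio was 0.937 and 0.960 at 0.5 h and 1 h and 0.831 to 0.902 at 10 to 24 h, and the actin ratio 0.956 and 0.995 against 0.987 to 1.43. These measures of RNA quality thus moved with the same windows as the lists above. With the GAPDH ratio as covariate the count was 1040, and 37 of the 92 named genes passed, among them ISG15, MX1, DNAJB9, LIG4, TAP1, ADM and TCF21 but not MYC, FEN1, COL3A1, THBS1, PSMC4 or TNFSF9. Without the 1 h array the count was 1827, and 60 of the 92 named genes passed in every leave-one-out fit, not including THBS1, SERPINH1, PLOD2, ZYX, FOS, CXCL8 and CDKN1A. With the actin ratio 81 of the 92 passed, not including CXCL8 and ZYX (adjusted p = 0.141 and 0.0558).

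Against 4 to 6 h, a comparison added after the data were seen, the 10 to 24 h arrays showed 8.02-fold higher DNAJB9 (adjusted p = 0.000896; 7 arrays against 2) and TNFSF9 higher by 3.14 ± 0.55. Asparagine synthetase, ASNS, rose by 2.57 ± 0.32 (adjusted p = 0.000882), and FICD, an enzyme that modifies the chaperone HSPA5, by 2.52 ± 0.39. The stress-induced gene DDIT4, at the floor on both 4 to 6 h arrays, was at least 3.56-fold higher. ZFP36, lower at 4 to 6 h than before, rose by 2.72 ± 0.41, and KLF10 by 2.05 ± 0.30. Of the largest falls, ADH1A, DHRS3 and CYP26A1 changed by -2.71 ± 0.81, -2.41 ± 0.58 and -1.97 ± 0.16, each lower on 7 of 7 later arrays than on both 4 to 6 h arrays. Such full separation held for 79 of the 81 named genes past the threshold. They were chosen from these same values, so it adds no support. IFIT1 measured -0.02 ± 0.15 (adjusted p = 0.912), whereas MX1 rose by 1.31 ± 0.21. The test called 3064 probe sets, 1617 higher and 1447 lower, a higher share of 52.8% that was 42.1% with scaling to the 75th percentile and 93.4% without normalization. The count was 872 without the 4 h array, 454 without the 6 h array, 338 without the 6 h and 18 h arrays, 1321 with the actin ratio as covariate and 4792 with array weights. Of 81 named genes past the threshold 46 passed with the actin ratio and 23 in every leave-one-out fit, the 23 including DNAJB9, ASNS, FICD, DDIT4, ZFP36, KLF10, CYP26A1 and MX1 but not TNFSF9, ADH1A or DHRS3. With the actin ratio ADH1A and DHRS3 did not pass either (adjusted p = 0.108 and 0.0613).

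A straight line on log2 hours over the 11 arrays asked which transcripts drifted through the whole course, and its values are fitted changes from 0.5 h to 24 h. TNFSF9 rose by 5.16 ± 0.76, DNAJB9 by 5.10 ± 0.68, ISG15 by 4.21 ± 0.36 (adjusted p = 3.51e-05) and IFI44, an interferon-induced gene, by 3.20 ± 0.44. TCF21 changed by -4.43 ± 0.35 (adjusted p = 1.84e-05), DKK1 by -4.01 ± 0.59, OSR2 by -3.98 ± 0.19 (adjusted p = 4.19e-07) and PRRX1, a mesenchymal homeobox gene, by -3.47 ± 0.65. THBS1 changed by -2.85 ± 0.61 and COL3A1 by -1.92 ± 0.28. By list, 1 of 37 measured genes rose and 11 fell among extracellular matrix genes (1 higher and 9 lower adjusted over the list alone, adjusted p = 0.00378, and adjusted p = 0.801 with an estimated correlation). Along the line 0 rose and 11 fell of 24 actin cytoskeleton and contractile genes (0 higher and 12 lower adjusted over the list alone, adjusted p = 0.0161, and adjusted p = 0.801 with an estimated correlation). Sterol and fatty acid synthesis genes had 1 rise and 10 falls of 23 (1 higher and 10 lower adjusted over the list alone, adjusted p = 0.0161, and adjusted p = 0.772 with an estimated correlation), among them the desaturase SCD at -1.74 ± 0.39. The sterol set did not pass without the 0.5 h array (adjusted p = 0.0547). Rises outnumbered falls among interferon-stimulated genes, by 15 to 1 of 34 (16 higher and 2 lower adjusted over the list alone, adjusted p = 0.00163, and adjusted p = 0.772 with an estimated correlation). The same held for unfolded protein response genes, by 11 to 1 of 16 (12 higher and 1 lower adjusted over the list alone, adjusted p = 0.00195, and adjusted p = 0.772 with an estimated correlation). Proteasome genes had 18 rises and 1 fall of 30 (18 higher and 1 lower adjusted over the list alone, adjusted p = 0.00141, and adjusted p = 0.801 with an estimated correlation), and heat shock genes 11 and 0 of 18 (11 higher and 0 lower adjusted over the list alone, adjusted p = 0.0161, and adjusted p = 0.772 with an estimated correlation).

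The line called 4423 probe sets, 2087 higher and 2336 lower with time. A spline that also follows a rise and later fall called 5862, of which 4011 were also called by the line, and the fitted maximum lay at 0.5 to 1 h for 2050, at 4 to 6 h for 1058 and at 10 to 24 h for 2754 of them. Its smallest p-values belonged to OTUD3, ANP32E, ASNS, HSPA13, OSR2, PTGIS, TGIF2 and TNFRSF11B, with fitted ranges of 2.60, 3.55, 3.20, 3.04, 3.87, 3.47, 2.66 and 2.96 log2 units. The spline also called IL6 (adjusted p = 0.0438) and COL1A1 (adjusted p = 0.00456), which the line did not (adjusted p = 0.134 and 0.114). The line's count was 2865 without the 1 h array and 934 with the GAPDH ratio, which fell along the course, as covariate, and 2652 with the actin ratio. The spline's was 3800 and 2989 with these ratios. Of 96 named genes past the line's threshold 80 passed in every leave-one-out fit, 70 with the actin ratio and 42 with the GAPDH ratio, with which THBS1, DKK1, PRRX1 and SCD did not pass (adjusted p = 0.137, 0.0558, 0.0907 and 0.303). With the actin ratio SCD did not pass either (adjusted p = 0.0516).

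Markers of cell types were followed by level and by change, and changes alone do not show which cells the cultures held. The mean log2 level of fibroblast markers was 13.08 at 0.5 h and 11.77 at 24 h. At 24 h it was 10.66 for keratinocyte, 9.93 for endothelial, 9.72 for leukocyte and 10.68 for 4 melanocyte markers. The median of all tested probe sets was 10.78. Fibroblast markers were the brightest of these lists on every array. Among fibroblast markers 4 of 9 fell along the line and none rose (adjusted p = 0.0256, and adjusted p = 0.772 with an estimated correlation): TCF21, PRRX1, the receptor PDGFRB at -1.22 ± 0.40 and the collagen receptor DDR2 at -1.20 ± 0.32. PDGFRB and DDR2 did not pass in every leave-one-out fit, and with the GAPDH ratio as covariate PRRX1, PDGFRB and DDR2 did not pass (adjusted p = 0.0907, 0.462 and 0.244). With the actin ratio PDGFRB and DDR2 did not pass (adjusted p = 0.466 and 0.154). Keratinocyte markers had 2 rises and 1 fall of 12, with the desmosome gene DSP at 2.30 ± 0.59, the keratin KRT10 at 1.36 ± 0.34 and the integrin ITGB4 at -1.37 ± 0.27. Endothelial markers had 1 rise and 1 fall of 9, and leukocyte markers 1 rise and 5 falls of 15, such as CD14 at -1.08 ± 0.25. With the GAPDH ratio as covariate DSP, ITGB4 and CD14 did not pass (adjusted p = 0.114, 0.171 and 0.146), and with the actin ratio DSP and KRT10 did not (adjusted p = 0.138 and 0.0786). As sets these 3 lists did not pass along the line (adjusted p = 0.688, 0.932 and 0.411). In the comparisons with 0.5 to 1 h neither they nor the fibroblast markers passed as sets. At 4 to 6 h 2 of 9 endothelial markers rose and 0 fell, and 2 of 12 keratinocyte markers rose and 1 fell. At 10 to 24 h 0 of 9 fibroblast markers rose and 3 fell, with a median of -0.78 (adjusted p = 0.0756, and adjusted p = 0.801 with an estimated correlation). The melanocyte list had fewer than 5 measured genes and was not tested. MITF, a transcription factor of melanocytes, measured -0.10 ± 0.14 (adjusted p = 0.593).

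**Figure D3:**
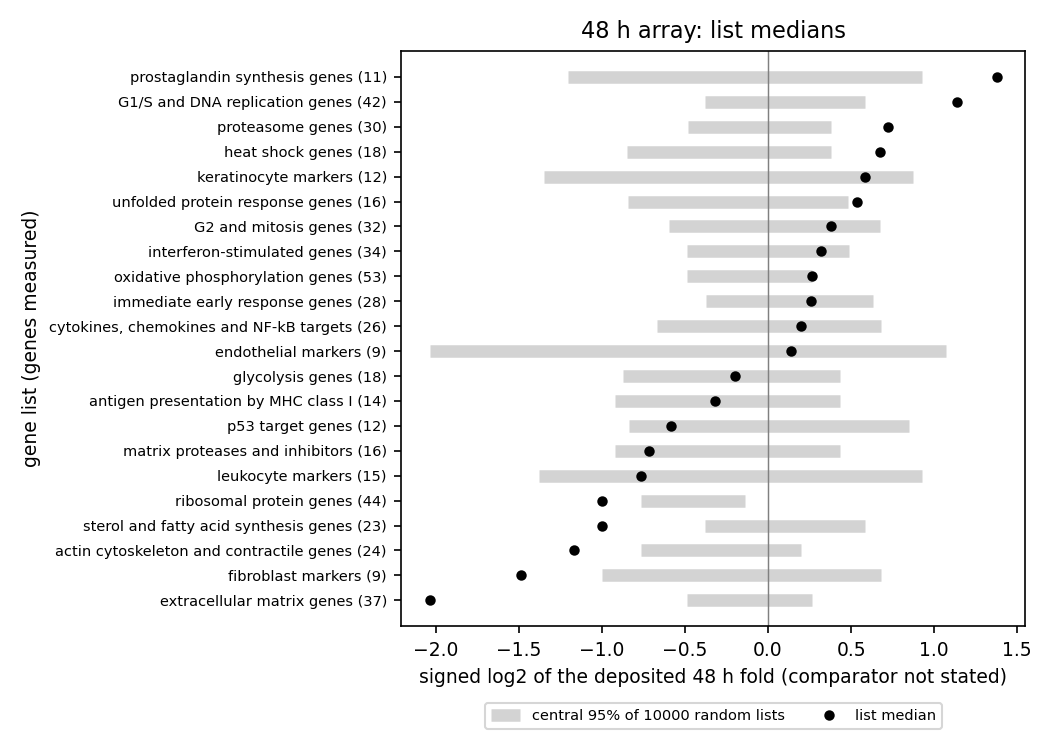
Median signed log2 of the deposited 48 h fold (horizontal axis) for each gene list (vertical axis, with the number of measured genes), with grey bars for the central 95% of medians of 10000 random lists matched on level. The extracellular matrix median of -2.04 lay below its bar and the G1/S and DNA replication median of 1.14 lay above its bar, sides that would swap with the sign of the fold. The bars do not allow for genes of a list moving together.

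At 48 h the values were the signed folds as deposited, from 1 array and with a direction that is not stated, so no test against other times was run. The lists were only ranked among random lists. Genes of a list can move together, which genes drawn singly at random need not do. The percentiles can therefore look too extreme and are not p-values. Of all 11353 tested probe sets, 21.3% had a 48 h fold at 2 or above and 29.1% at -2 or below. With the sign of the fold turned, every fold and median would change sign, and a percentile near 0 would lie near 100 and the reverse, so the values show only which genes and lists lay on opposite sides. Single genes below were chosen after their values were seen. The largest folds in size with a negative sign were those of COL1A1, a chain of type I collagen, at -210.1, GAS6 at -177.6 and IGFBP3, an insulin-like growth factor binding protein, at -172.6. Other probe sets of these genes had smaller folds, -4.9 for COL1A1, -8.6 and -9.1 for GAS6 and -12.3 for IGFBP3. Of 37 extracellular matrix genes 25 were at -2 or below and 2 at 2 or above, and the median signed log2 of -2.04 lay at percentile 0 of 10000 random lists matched on level. The actin list had a median of -1.17 (percentile 0.015) and fibroblast markers -1.49 (percentile 0.425). Of sterol and fatty acid synthesis genes 12 of 23 were at -2 or below (percentile 0.175), and of ribosomal protein genes 24 of 44 (percentile 0). On the other side, 28 of 42 G1/S and DNA replication genes were at 2 or above, among them the chromatin assembly gene CHAF1B at 19.5 and CCNE1 at 14.8, with a list median of 1.14 (percentile 100). Prostaglandin synthesis genes had a median of 1.38 (percentile 99.915), with the prostaglandin E synthase PTGES at 51.1 and PLA2G4A at 13.9, but PTGIS, prostacyclin synthase, at -15.9. Proteasome genes lay at 0.72 (percentile 99.98), heat shock genes at 0.68 (percentile 99.875) and unfolded protein response genes at 0.54 (percentile 98.595).

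The interferon-stimulated list had a 48 h median of 0.32 (percentile 89.55), with ISG15 at 8.6 and MX1 at 9.2, whereas another interferon-induced gene, IFITM2, was at -133.7. The remaining medians were 0.26 for oxidative phosphorylation, 0.38 for G2 and mitosis, 0.26 for immediate early, 0.20 for cytokine, -0.32 for antigen presentation, -0.58 for p53 target, -0.72 for matrix protease, -0.20 for glycolysis, 0.58 for keratinocyte, 0.14 for endothelial and -0.77 for leukocyte genes, at percentiles from 5.32 to 96.9. Of the probe sets called higher at 10 to 24 h than at 0.5 to 1 h, 78.0% had a positive 48 h fold, and of those called lower 55.4% had a negative fold, against 51.4% and 48.6% of all tested probe sets. With the sign of the fold turned, the first pair of shares would be 22.0% and 44.6%. GAP43 was called lower at 10 to 24 h and had a 48 h fold of 23.7. Across probe sets, which are not independent replicates, the Spearman correlation of the signed 48 h log2 fold with the change from 0.5 to 1 h was -0.05 at 6 h, 0.10 at 10 h and 0.33 at 24 h, and these would change sign with the fold. Because the comparator and direction are not stated, these values do not show whether changes went on to 48 h, and the folds were not compared in size with differences between the other arrays.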

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

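No explanation is weighed in this part, and the series searched and the genes named were chosen after the data were seen. Within the 7 arrays of 10 to 24 h, 49 series of values (control probe sets, list means and the 15 panel genes) were searched for a lone array by Dixon's ratio of its gap to the range, against the 95% critical value for 7 arrays, which chance exceeds in about 1 of 20 series. The 4 found all belonged to control probe sets, and no gene list or panel gene was among them. The 5′ probe set of 18S ribosomal RNA read 4887 at 18 h against 1049 on the next highest array (ratio 0.823), and its middle probe set read 3380 against 882 (ratio 0.778). Outside this window, the same 5′ probe set read 9039 at 6 h and the antisense actin control 10690 at 6 h. The spiked-in bacterial transcript BioB read 5371 at 10 h against 3087 (ratio 0.639), and BioC read 8889 against 4435 (ratio 0.679).

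Among the probe sets blank on the 11 intensity arrays, 414 non-control probe sets had a 48 h fold, and 302 of them were at 2 or more in either direction, 81 positive and 221 negative. Examples chosen after their values were seen were UBE3A at 118.8, RRAGD at 65.6 and IGFBP5 at -80.9. Other UBE3A probe sets, with intensities, had folds of -9.5, 1.8 and 1.4. These probe sets have no intensity to set beside the folds.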

How the results depend on the processing

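No paired analysis was possible because each time had 1 array. For named genes over 27 settings, 6851 values stayed on their side of the threshold, 847 for 212 results no longer passed and 19 for 8 results newly passed, all in the direction first found. 1 that had passed reversed, ENO2 at 10 to 24 h against 0.5 to 1 h, at -0.10 with the GAPDH ratio as covariate (adjusted p = 0.932). For list calls, 222 values stayed and 33 no longer passed. With the GAPDH ratio as covariate the counts were 934 for the trend, 3800 for the spline, 276 for 4 to 6 h and 1040 for 10 to 24 h against 0.5 to 1 h, and 3888 (against 3064) for 10 to 24 h against 4 to 6 h. With the actin ratio (chosen after seeing the data) they were 2652, 2989 and 1009 for the trend, spline and 4 to 6 h, and 1321 for 10 to 24 h against 4 to 6 h. Both ratios moved with time, so these fits also remove change that runs with time. Array weights gave 1478 for 4 to 6 h against 0.5 to 1 h and 4792 for 10 to 24 h against 4 to 6 h. Leave-one-out counts ran from 2865 (without 1 h) to 4620 for the trend, 4973 to 5833 for the spline, 51 (without 6 h) to 832 for 4 to 6 h (60 without 1 h, 237 without 4 h, 445 without 16 h), 1827 (without 1 h) to 4840 for 10 to 24 h against 0.5 to 1 h, and 454 (without 6 h; 872 without 4 h) to 3745 for 10 to 24 h against 4 to 6 h. A window of 2 arrays is left with 1 array in such fits, which is assumed to vary like the others. Without the 6 h and 18 h arrays (chosen after seeing the data) the counts were 37 for 4 to 6 h against 0.5 to 1 h and 338 for 10 to 24 h against 4 to 6 h. List calls numbered 0 with an estimated correlation, and 11 (without 0.5 h) to 19 in leave-one-out fits, against 17. Beyond the fewer arrays in these fits, the cause was not tested. All alternatives of the 48 h contrast, and leaving out the 48 h array, were not run because that array holds folds. Signal near the floor of 315 limits dim probe sets.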

Other observations

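The genes named in this part, the orders of times, the step at 18 h and 24 h, the contrast of 10 h and 12 h with 6 h and 14 h, the comparison of spiked-in controls, and the counts within groups of genes under other scalings and with the GAPDH ratio were chosen after the data were seen. IFIT3, of the interferon list, read 2630 at 0.5 h, 20845 at 6 h, 25022 at 10 h and 5283 at 24 h. IL6 read 2358 at 6 h, 7905 and 8875 at 10 h and 12 h, and 1944 at 14 h. TNFSF9 climbed from 669 at 6 h to 1950 at 10 h and 9923 at 24 h, and FOS fell from 21769 at 0.5 h to 6501 at 1 h. Each is 1 array per time, without a replicate.

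Other orders of the 11 times were fitted to ask whether the counts could arise by chance. In 100 orders, the real one included, only the real order (1 of 100) gave as many probe sets: 4423 against at most 2819 for the trend, 5862 against 2133 for the spline, 668 against 216 for 4 to 6 h, 4368 against 2905 for 10 to 24 h against 0.5 to 1 h, and 3064 against 1965 for 10 to 24 h against 4 to 6 h. A random order of the arrays is thus an unlikely source of these counts, though 100 orders cannot show a share below 1 of 100. A technical drift that follows time is not addressed, since shuffling the arrays breaks it up as well.

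The rise of interferon and unfolded protein response genes at 10 to 24 h, 31 genes in all, was set against RNA quality, for which the 18 h and 24 h arrays had the highest actin 3′ over 5′ ratios, 0.33 log2 above the 16 h and 20 h arrays, more than the 0.22 between 10 to 24 h and 0.5 to 1 h. If falling RNA integrity, as the actin ratio tracks it, were the whole cause, the 31 genes should be higher still on those arrays. Their median step was instead -7.44% of the fitted rise (quartiles -28.2% and 1.52%), and 8 of 31 were higher. That argues against it only as the whole cause for these genes. A part in the rise is not addressed, because list means also changed with time. The interferon list mean fell from 1.21 at 12 h to 0.77 at 16 h. The GAPDH ratio moved the other way, falling with time. With it as covariate 31 of 31 were still higher, by a median of 1.31 against 1.09. Of these 14 passed, with a median error over the 31 of 0.35 against 0.21. Because the GAPDH ratio itself separated the 2 windows, a drift tied to it is not excluded for any of the 31. Without quantile normalization 31 of 31 still passed and were higher, which argues against that step as the source of the rise. With scaling to the 75th percentile 21 interferon-stimulated genes rose and 0 fell, and 11 unfolded protein response genes rose and 1 fell. Any scaling by the authors remains in all these values, so its part was not tested. A biological response to infection stays open as a hypothesis, since no uninfected array was measured and time in culture may act alike.

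The fall of 7 immediate early genes by 4 to 6 h was set against normalization and handling. With scaling to the 75th percentile 6 of 7 still passed and were lower. KLF10 did not, at -1.40 ± 0.38 (adjusted p = 0.0511) against -1.46 ± 0.37 after quantile normalization, because a slightly smaller fold with nearly the same error moved its p past 0.05. Without normalization 7 of 7 passed. Handling of the cultures at infection, such as a change of medium, may induce the same genes in uninfected cells, and with no uninfected array it cannot be told apart from infection for any of the 7.

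Levels at 10 h and 12 h were set against those at 6 h and 14 h because IL6 stood out, by 1.97 log2. Of the 26 cytokine, chemokine and NF-kB target genes 15 were higher, by a list median of 0.14 log2, but the list mean was highest at 4 h (0.29), whereas of interferon-stimulated genes 28 of 34 were higher, by a median of 0.30, with the highest list mean at 12 h (1.21). The cytokine list's percentile of 99.07 among random lists cannot speak to a shift of all probe sets alike, which quantile normalization removes beforehand. Of spiked-in controls 0 of 4 were higher at both 10 h and 12 h than at both 6 h and 14 h, so their deposited signal was not raised jointly at these times. BioB and BioC read 2703 and 3404 at 12 h, where IL6 read 8875, and 5371 and 8889 at 10 h, where IL6 read 7905. The control readings were not normalized and the IL6 values were. The controls therefore cannot decide whether a property of these arrays lay behind the IL6 values. A brief response may be a hypothesis, as may a culture or infection that differed at these times, which was not tested.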
